A study of Mus musculus with 52 samples.

How the data were processed

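The samples were mouse embryonic fibroblasts of 1 genotype, heterozygous for CReP and wild type for GADD34 per the labels; both proteins are regulatory subunits that direct a phosphatase to the translation factor eIF2 alpha. Cells were left untreated, exposed to thapsigargin (Tg, an inhibitor of the calcium pump of the endoplasmic reticulum, ER) for 0.5, 1, 2 or 4 h, or exposed to dithiothreitol (DTT, a reducing agent that breaks disulfide bonds) for 30 min followed by 0, 10 or 20 min of recovery. Cells were then separated into an ER and a cytosol fraction. The labels list 52 samples in 26 groups of 2 replicates, of which 40 belong to the Tg series (20 of ribosome footprints and 20 of mRNA) and 12 to the DTT series. The labels of the 12 DTT samples do not name the assay, although the DTT table holds columns of both kinds.

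Per the labels, footprints were made by nuclease digestion, pelleting of ribosomes and gel purification, and mRNA libraries by depletion of ribosomal RNA and fragmentation. The submitters' processing notes name the aligner Bowtie without a version, and the genome build is not given in the sources used here. The authors deposited 2 gene tables, 1 for Tg and 1 for DTT, with 3 header lines and 22417 genes each. In both tables the deposited translation and mRNA columns hold a score, scaled by the authors in a way the headers do not state, with 1 pooled value per gene and group. The deposited ribosome density columns hold a ratio of translation to mRNA. A further deposited column of TRUE or FALSE, with no header over it (unit other), divides the genes into 8434 called marked here and 13983 called unmarked. Genes without a value are blank, and what a blank stands for is not stated. No counts and no values per replicate were analysed here, so the depth behind each value is unknown and its counting precision cannot be given.

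The ER and cytosol columns carry separate constants. The untreated columns of the DTT table equal those of the Tg table times 0.913 in the ER and 1.06 in the cytosol, with the same blanks, so both tables rest on the same untreated data. A difference between ER and cytosol therefore has no absolute zero, and is given beside the median of all genes or as marked minus unmarked genes, which such constants hardly move. ER shares and sums of both fractions take the authors' scale as it stands.

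Comparisons used log2(value + 1) of genes with a value in every column of that assay and table. This left 9323 genes for Tg footprints (1398 marked), 2389 for Tg mRNA (212 marked), 2245 for translational efficiency (footprints over mRNA, 161 marked), 8315 for DTT footprints (1334 marked) and 2133 for DTT mRNA (215 marked). Because of the blanks, many abundant mRNAs of secreted proteins, such as Col1a1, drop out of the mRNA comparisons. The comparisons were ER against cytosol in untreated and DTT-treated cells, treated against untreated (or recovering against DTT-treated) cells as the mean of the ER and cytosol differences, and the ER shift, which is the ER difference minus the cytosol difference. The 28 comparisons, the gene lists, the 13 genes that are always named and the alternatives given below as planned were chosen before the data were examined. The 5 DTT comparisons among them were planned without an assay and run for both, which makes 33.

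The planned tests need replicates and were not run. Genes called uncertain were judged from their name or family to have near-identical copies, and whether they share reads was not tested. In place of the tests a gene counts as over 2-fold when its log2 difference exceeds 1 in size, and no difference is called tested. Intervals on marked minus unmarked medians are 95% bootstrap intervals from 2000 resamples of genes, and describe the spread over genes only. Of the 25 lists, those with at least 5 complete genes are given with their median, quartiles and percentile among 10000 random lists matched on expression in 10 bins, as a description. Named genes were the 8 highest and the 8 lowest genes over 2-fold, with a mean level above the median gene, at the time with the most genes over 2-fold. For averaged comparisons they also had to go the same way in both fractions. Up to 4 members over 2-fold exemplify each list, or the 2 most abundant members where none was, and other genes named were chosen after their values were seen. Some genes that meet these rules are not reported here.

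Tested on simulated data with a noise SD of 0.25, the footprint ER shift put 73% of genes with a true log2 shift of -1.5 over 2-fold, with a median estimate of -1.27, and 2.51% of genes without a shift. At a true shift of -3 it put 100% over 2-fold, with a median estimate of -2.52. The noise SD was set by hand, alike for all genes, and was not estimated from these data. These shares therefore describe that setting and are not error rates of the comparisons below.

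Alternatives run as planned were a pseudocount of 0.1, a strict filter (mean log2 level above that of the median gene) and no filter on blanks in columns outside the comparison. Alternatives chosen after seeing the data were blanks taken as 0, columns centred on their median gene, the log2 of the sum of ER and cytosol, and the deposited density. Counts given after centring in the report subtract the median difference over genes, which is another centring than that of the columns. Alternatives that need counts or replicates were left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.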

Results

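Ribosome footprints and mRNA were measured in ER and cytosol fractions of mouse embryonic fibroblasts, untreated or under agents that disturb protein folding in the ER. The Tg table covers untreated cells and 4 times of Tg. The DTT table covers the same untreated cells, cells after 30 min of DTT, and cells after 10 and 20 min of recovery. Each group was made of 2 replicates but is given as 1 pooled score, so no difference could be held against a spread between replicates, and the depth is unknown. Footprint columns held between 9205 and 12676 genes with a value, and mRNA columns between 3596 and 5357. Of the listed genes found in the tables, the marked ones included 22 of 22 ER chaperones, 53 of 54 extracellular matrix and secreted proteins, 37 of 37 surface proteins and 26 of 26 lysosomal proteins. They included 0 of 80 ribosomal proteins and 0 of 31 proteasome subunits. Genes named below as the highest or lowest of a comparison rank among those with a mean level above that of the median gene, while genes given as examples of a list do not have to meet that limit.

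In untreated cells, footprints of the listed matrix and secreted, surface and lysosomal proteins lay almost wholly in the ER fraction, which addresses how far the fractionation separates the mRNAs of the secretory pathway. Marked genes as a whole were more mixed, with a median ER share of 92.1% and a lower quartile of 59.2%. Among the genes with the highest ratios of ER to cytosol were Col1a1, a chain of type I collagen (log2 difference 6.92), the ER chaperone Hsp90b1 (6.86) and the disulfide isomerases P4hb (6.70) and Pdia3 (6.66). The secreted glycoprotein Fstl1 (6.70), the matricellular protein Cyr61 (6.65) and Mfge8, a secreted bridge to dying cells (6.63), were also among the 8 highest. Among the 8 lowest were Nutf2, which carries Ran into the nucleus (-2.07), and the ribosomal protein Rpl29 (-2.03). Actg2 (-2.20), the histone H3f3b (-1.91), Gm10349 (-2.02), LOC637657 (-1.94), Gm6155 (-1.93) and Gm8290 (-1.90) complete the 8 lowest and are uncertain.

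By list, all 19 ER chaperones and folding enzymes were over 2-fold higher in the ER, with a median of 5.30 and Calr, the calcium-binding chaperone, at 6.60. The same held for 48 of 48 extracellular matrix and secreted proteins (median 5.23; Sparc 6.47), 30 of 30 surface proteins (median 5.05; the transferrin receptor Tfrc 6.43, Bsg 6.43, the integrins Itgb1 6.37 and Itgav 6.19) and 22 of 22 lysosomal proteins (median 4.75; Psap 6.40 and the cathepsins Ctsb 6.30, Ctsl 6.22 and Ctsd 6.04). The ER entry and secretory transport machinery was mixed, with 24 of 36 genes over 2-fold higher and 3 lower around a median of 3.54. Its highest genes were membrane subunits, namely Rpn2 (6.05), Rpn1 (5.98) and Ddost (5.80) of the oligosaccharyltransferase and the translocon channel Sec61a1 (5.67). ER-associated degradation had 11 of 16 higher (median 2.45; Derl1 4.89, Os9 4.48, Sel1l 3.95), and the targets of IRE1-dependent decay 4 of 5 (median 3.65; Col6a1 5.40, Pmp22 3.84, Pdgfrb 3.65, Galnt10 2.11). Cholesterol synthesis was split, with 10 of 20 genes higher (Scd2 6.08, Scd1 5.53, Cyp51 5.48) and 0 lower. Its median of 0.92 was -0.11 under the strict filter.

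The remaining lists had medians below the -0.48 of all genes, except for immediate early genes and mRNAs with upstream reading frames. Medians were -0.99 for 80 ribosomal proteins (39 lower; Rps20 -1.60, Rpl23a -1.45), -0.96 for 31 proteasome subunits (13 lower; Psma4 -1.32, Psmd11 -1.22), -0.93 for 34 glycolytic and cytoskeletal genes (15 lower; Tmsb4x -1.66), -0.84 for 29 translation factors and -0.69 for 73 subunits of oxidative phosphorylation (17 lower; Ndufb3 -1.70, Cycs -1.69). Single members stood apart, such as the actin crosslinker Flna (2.25), the scaffold Eif4g1 (1.66), the proliferation antigen Mki67 (1.76) and the glutaminyl-tRNA synthetase Qars (2.55). Among ATF4 and CHOP targets (20 genes, median -0.76), both chains of an amino acid transporter, Slc7a5 (5.05) and Slc3a2 (3.80), were over 2-fold higher in the ER. Medians were -0.87 for 14 NRF2 targets and metallothioneins, -0.73 for 26 cell cycle genes, -0.69 for 20 cytosolic aminoacyl-tRNA synthetases, -0.58 for 18 cytosolic heat shock genes and -0.23 for 21 immediate early genes. For 8 mRNAs with upstream reading frames the median was -0.09. In that last list the phosphatase subunit Ppp1r15b (CReP) stood at 2.33, while Ppp1r15a (GADD34) stood at -0.24, Atf4 at -0.95 and Ddit3 at 0.06. Over 9323 genes the median was -0.48, with 1142 genes over 2-fold higher and 1271 lower, or 1368 and 103 after centring on that median. The medians of marked and unmarked genes were 2.80 and -0.57, a difference of 3.37 (95% interval over genes 3.17 to 3.50).

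The mRNA of secretory pathway genes also lay toward the ER. The 8 highest genes were Hsp90b1 (5.69), the collagen Col5a2 (5.61), Itgb1 (5.20), Pdia3 (4.73), Aplp2 (4.60), the cytokine receptor subunit Il6st (4.60), the lectin chaperone Canx (4.59) and calumenin, Calu (4.57). The 8 lowest, Hist1h4h (-1.93), Rpl32 (-1.78), Rps15a-ps5 (-1.75), LOC100504872 (-1.73), Hist2h3c1 (-1.71), LOC674595 (-1.65), Hist2h3c2 (-1.61) and Rps15a (-1.52), are histones, ribosomal proteins or their copies and are uncertain. All 8 ER chaperones with complete values were over 2-fold higher in the ER (median 4.27), as were 5 of 5 surface proteins (3.82; Cd44, the hyaluronan receptor, 4.28) and 5 of 5 matrix and secreted proteins (3.48; Sparc 4.03). ER entry genes had a median of 1.37, with 8 of 14 higher (Sec11a 3.41, Ssr3 3.39), while 68 ribosomal proteins had a median of -0.44 and 24 proteasome subunits of -0.21. Over 2389 genes, 288 were over 2-fold higher in the ER and 66 lower, and marked minus unmarked genes came to 1.13 (0.77 to 1.38). With blanks taken as 0 that difference was 3.32 (2.25 for footprints), and without the filter on blanks elsewhere it was 0.79.

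Footprints per mRNA were also higher in the ER for ER chaperones, surface proteins and most matrix and secreted proteins. Among genes above the median level, the 8 highest were the lysosomal membrane protein Lamp1 (3.67), Sco2, a copper chaperone of cytochrome oxidase (3.25), Tmem45a (3.22), the collagen hydroxylase P4ha1 (3.19), the chemokine Cxcl5 (3.09), Pigf, which acts in GPI anchor synthesis (2.96), Ssr1 of the translocon (2.95) and the tetraspanin Tspan31 (2.69). The lowest were the transcription factor Elf1 (-3.31), the assembly factor Cox20 (-2.77), Lyrm2 (-2.29), the ubiquitin ligase Stub1 (-2.29), Sugt1 (-2.20), Ppp2r2a (-2.15), LOC101056341 (-2.11, uncertain) and Cdca8 (-2.09). All 8 ER chaperones (median 2.00; P4hb 2.49, Calr 2.33) and all 5 surface proteins (1.85; the receptor kinase Axl 2.35) were over 2-fold higher, as were 4 of 5 matrix and secreted proteins (2.23; the stromelysin Mmp3 3.58, Sparc 2.44). Of 21 oxidative phosphorylation subunits, 10 were lower and 0 higher (median -0.99; Atp5f1 -1.76). Ribosomal proteins had a median of -0.55, and ER entry genes of -0.03, which was 0.14 without the filter on blanks elsewhere and 0.87 under the strict filter. Over 2245 genes the median was -0.61, with 100 genes higher and 526 lower (177 and 84 after centring), and marked minus unmarked genes came to 1.77 (1.53 to 2.11).

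Within 0.5 h of Tg, footprints of secretory pathway genes were lower in the ER and far higher in the cytosol relative to untreated cells. The ER shift, the log2 change in the ER minus that in the cytosol, was lowest, among genes above the median level, for the acute-phase protein Saa1 (-7.66), the proteoglycan decorin, Dcn (-7.52), Saa3 (-7.04), the lysosomal membrane protein Lamp2 (-6.95), the protease inhibitor Serpine2 (-6.77), Pdia3 (-6.73), P4ha1 (-6.68) and Fstl1 (-6.60). Decorin had 96.6% of its footprint score in the ER in untreated cells and 11.2% at 0.5 h. Fibronectin, Fn1, went from 98.4% to 55.7%, and Hspa5, the chaperone BiP, from 98.9% to 60.8%. Among the 8 highest shifts were those of Ubald2 (3.28), the histones Hist1h2bk (1.99) and Hist2h2be (1.55), Litaf (1.54), Tssc4 (1.44), Szrd1 (1.30) and the chromatin protein Hmga1 (1.28). The histones and Hmga1 are uncertain.

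By list at 0.5 h, 19 of 19 ER chaperones were over 2-fold lower (median -5.35; P4hb -6.51, Hsp90b1 -6.49, Calr -6.32), as were 48 of 48 matrix and secreted proteins (-5.18; Lgals3bp -7.43, Lum -6.93, Bgn -6.47), 22 of 22 lysosomal proteins (-4.87; Ctsb -6.41, Ctsl -6.18) and 30 of 30 surface proteins (-4.31; Itgb1 -6.42, Tfrc -6.32). ER entry genes were lower in 30 of 36 (-3.97; Rpn1 -5.88, the cargo receptor Lman1 -5.64), IRE1-dependent decay targets in 4 of 5 (-3.39), ER-associated degradation in 10 of 16 (-2.40; Derl1 -4.47) and cholesterol synthesis in 11 of 20 (-1.57; Sc4mol -4.94). Ribosomal proteins, at -0.40 (6 of 80 lower), and proteasome subunits, at -0.50 (3 of 31), lay near the median of all genes. Oxidative phosphorylation, of whose 73 genes 25 are marked, stood at -0.69 (23 of 73 lower). The other lists had medians of -0.65 for translation factors (Pabpc1, the poly(A)-binding protein, -1.89), -0.62 for aminoacyl-tRNA synthetases (Qars -3.03), -0.57 for NRF2 targets (Fth1 -1.53), -0.57 for heat shock (Hspd1 -1.54), -0.56 for cell cycle (Mki67 -2.03), -0.30 for glycolysis and cytoskeleton (Flna -2.01), -0.28 for ATF4 and CHOP targets (Slc7a5 -4.83, Slc3a2 -3.22), -0.23 for mRNAs with upstream reading frames (Ppp1r15b -2.29) and -0.05 for immediate early genes (Ier3 -2.82).

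The shift was nearer 0 at each later time for the 4 lists with the lowest medians at 0.5 h. For ER chaperones the medians were -2.96, -2.21 and -0.49 at 1, 2 and 4 h, for matrix and secreted proteins -2.28, -1.86 and -0.81, for surface proteins -2.62, -2.05 and -1.00, and for lysosomal proteins -2.68, -2.16 and -0.71. The median ER share of ER chaperone footprints was 98.5% in untreated cells and 55.0%, 86.4%, 91.5% and 96.2% at the successive times, while that of ribosomal proteins was 33.4%, 28.2%, 31.4%, 34.3% and 36.9%. For Hspa5 the ER score was 711 untreated and 707 at 0.5 h, while the cytosol score was 7.72 and then 457. It reached 3793 in the ER and 23.8 in the cytosol at 4 h. Col1a1 went in the ER from 827 to 194 and in the cytosol from 5.85 to 112 at 0.5 h, and stood at 378 and 4.38 at 4 h.

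**Figure D1:**
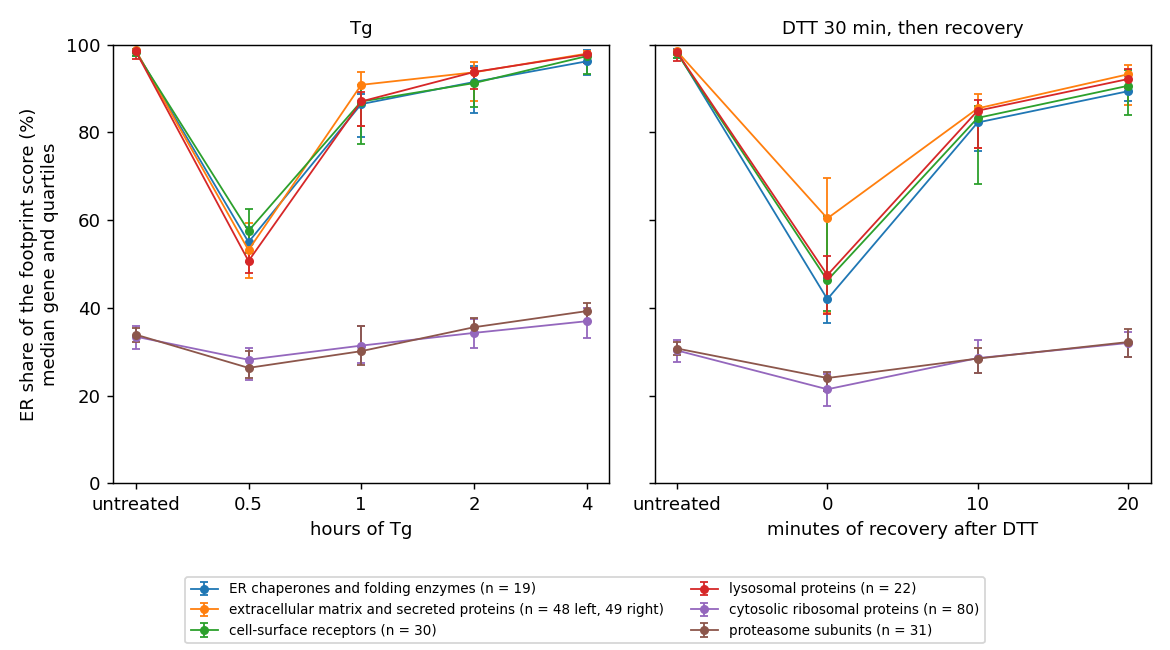
ER share of the footprint score (percent of ER plus cytosol, median gene with quartiles) for 6 gene lists by hours of Tg and by minutes of recovery after DTT. The share of ER chaperones was 98.5% untreated and 55.0% at 0.5 h of Tg, while that of ribosomal proteins stayed between 28.2% and 36.9% under Tg.

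Marked genes had a median ER shift of -2.74 at 0.5 h against -0.33 for unmarked genes, a difference of -2.42 (-2.59 to -2.28). It came to -1.53, -1.29 and -0.64 at 1, 2 and 4 h. With blanks taken as 0 the 4 values were -0.88, -0.82, -0.74 and -0.52. For marked genes the ER medians were -0.84, -0.39, -0.43 and -0.08 and the cytosol medians 1.90, 1.15, 0.73 and 0.26, while the sum of both fractions stood at -0.11, -0.12, -0.26 and -0.06. At 0.5 h 80 genes were over 2-fold higher and 1933 lower (361 and 1244 after centring on the median of -0.41). The counts were 293 and 1330 at 1 h (521 and 1089 centred), 99 and 972 at 2 h, and 161 and 362 at 4 h (81 and 474 centred). The cytosol values at 0.5 h carry a limit. Among marked genes found mainly in the ER, 34.01% had a deposited density over 1.5 times or below 0.5 times the ratio of the deposited scores, against 2.22% of unmarked genes at matched mRNA levels. Footprint levels were not matched. In the ER at 1 h these shares were 9.95% and 2.88%. In the cytosol of untreated cells, the reference, they were 3.88% and 0.42%, and in the cytosol at 1 h 3.76% and 1.80%.

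**Figure D2:**
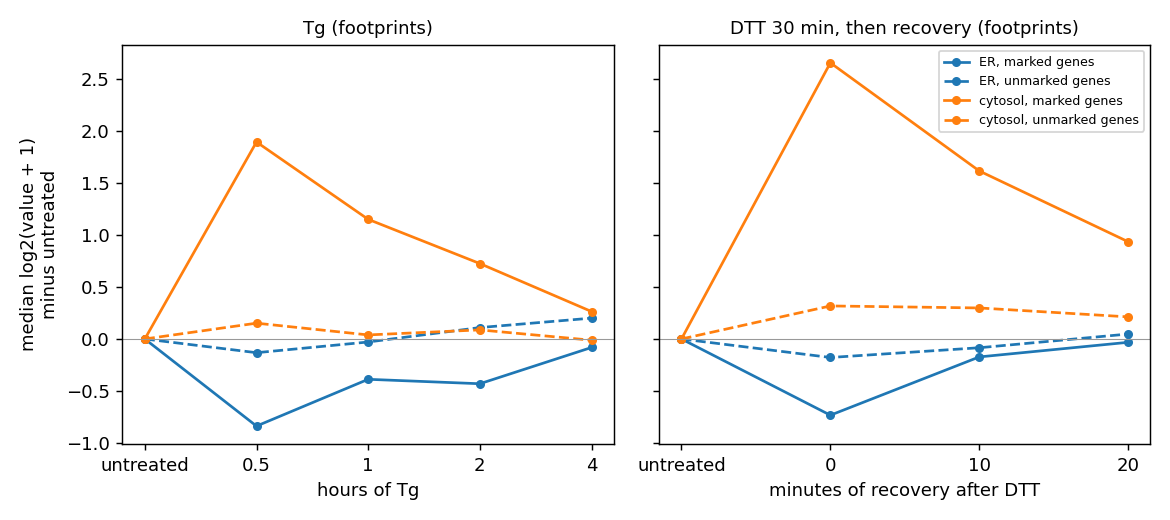
Median log2 difference from untreated cells of footprint scores in the ER and the cytosol, for marked and unmarked genes, by hours of Tg and by minutes of recovery after DTT. Marked genes stood at -0.84 in the ER and 1.90 in the cytosol at 0.5 h of Tg, and at -0.08 and 0.26 at 4 h.

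The mRNA of the secretory pathway showed the same kind of shift at 0.5 h of Tg. The 8 lowest genes were Hsp90b1 (-5.45), Canx (-4.85), Itgb1 (-4.83), Col5a2 (-4.67), the acid ceramidase Asah1 (-4.63), Sparc (-4.62), Calu (-4.60) and Pdia3 (-4.55). All 8 ER chaperones were over 2-fold lower (median -4.50), as were 5 of 5 matrix and secreted proteins (-3.76), 4 of 5 surface proteins (-3.25) and 11 of 14 ER entry genes (-1.84; Sec11a -4.31, Tmed2 -3.82). Oxidative phosphorylation had 11 of 21 lower (-1.15; Cox4i1 -2.71) and ribosomal proteins 16 of 68 (-0.73; Rpl22 -2.10). The 8 highest were LOC100862446 (1.498), Rpl36a (1.48), Rps15a-ps5 (1.45), the mitochondrial ribosomal protein Mrpl24 (1.42), the clathrin light chain Clta (1.42), Rbm28 (1.31), Fra10ac1 (1.22) and Nucks1 (1.16), of which the first 3 are uncertain. Marked minus unmarked genes came to -0.90 at 0.5 h, and to -0.85, -0.71 and -0.48 at 1, 2 and 4 h. Over 2-fold, 26 genes were higher and 732 lower at 0.5 h (155 and 242 after centring on -0.66), 164 and 251 at 1 h, 164 and 216 at 2 h, and 174 and 117 at 4 h (129 and 161 centred). The share of ER chaperone mRNA in the ER was 95.2% untreated, then 48.6%, 77.8%, 84.0% and 94.3%.

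Footprints of Ppp1r15a, Ddit3 and Atf4 were over 2-fold higher at 0.5 h of Tg than in untreated cells, which addresses how translation responds over the course of ER stress. The 8 highest genes at 0.5 h included Ppp1r15a (mean log2 difference of ER and cytosol 3.83), the growth factor-like Ctgf (3.55), the prostaglandin synthase Ptgs2 (3.53), the calcineurin regulator Rcan1 (3.47), the transcription factors Ddit3 (CHOP, 3.07) and Atf4 (2.97), 1500012F01Rik (4.12) and LOC100861722 (4.55), the last uncertain. The sum of both fractions was smaller for Ctgf (1.86; ER 1.48, cytosol 5.62) and Ptgs2 (1.67; ER 0.92, cytosol 6.14). Of 8 mRNAs with upstream reading frames, 5 were over 2-fold higher at 0.5 h (median 2.58; Slc35a4 2.94), with medians of 2.38, 1.53 and 1.95 at 1, 2 and 4 h. The ER score of Ddit3 was 5.06 untreated and then 44.7, 134, 120 and 128, and that of Atf4 44.5 and then 373, 389, 652 and 588. ATF4 and CHOP targets came later, with medians of 0.13, 0.52, 0.71 and 1.41 and 12 of 20 higher at 4 h (Ddit3 4.47, Ppp1r15a 3.98, Atf3 2.995, the pseudokinase Trib3 2.82). Ddit3, Ppp1r15a and Atf5 are on both lists. Immediate early genes were high early, with medians of 1.03, 1.26, 1.03 and -0.01. At 0.5 h 11 of 21 were higher (Ier3 2.53, Fos 2.09, Ier2 2.04, Nr4a1 1.95), and at 4 h Egr1 (-1.91) and Jun (-1.10) were over 2-fold lower while Myc (1.23) and Maff (1.02) were higher.

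**Figure D3:**
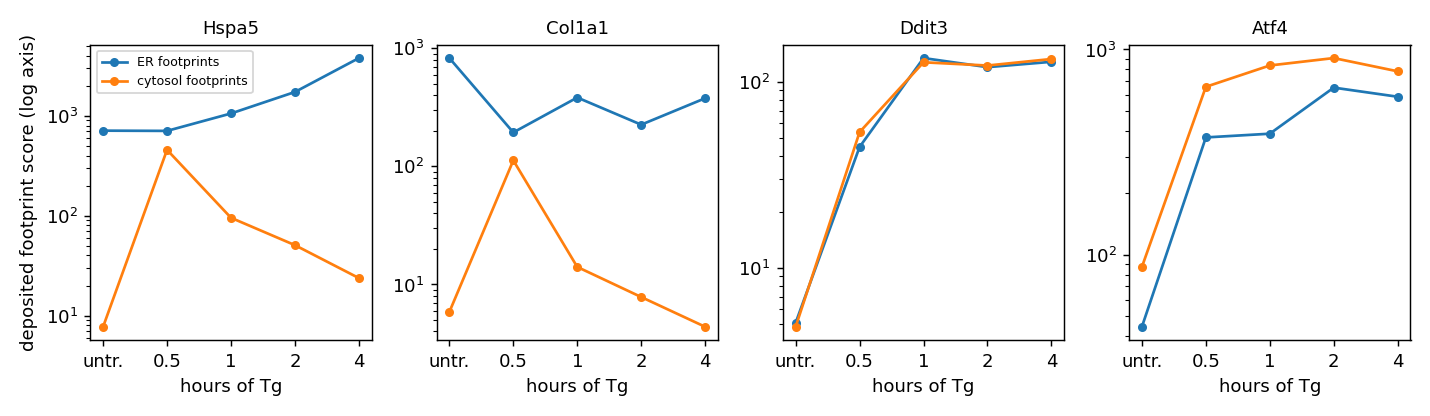
Deposited footprint scores (log axis) of Hspa5, Col1a1, Ddit3 and Atf4 in the ER and the cytosol by hours of Tg. Hspa5 went from 7.72 to 457 in the cytosol at 0.5 h and from 711 to 3793 in the ER at 4 h, and Ddit3 went from 5.06 to 128 in the ER over the same 4 h.

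ER chaperones and folding enzymes had a median of 0.97 at 4 h, with 9 of 19 over 2-fold higher (Sdf2l1 3.18, Manf 2.44, Hspa5 1.96, Creld2 1.81). At the earlier times the averaged medians were 1.32, 1.04 and 0.96, while the sums of both fractions had medians of -0.32, -0.11, -0.01 and 0.84 from 0.5 to 4 h. Herpud1, a stress-induced ER membrane protein (3.46), and Vimp (1.58) led ER-associated degradation at 4 h (median 0.44), and aminoacyl-tRNA synthetases stood at 0.74 (Tars 1.12, 1 of 20 over 2-fold). The summed footprints of Xbp1, the transcription factor activated by IRE1, stood at 0.24, 1.21, 2.26 and 2.36. The ER score of the cochaperone Dnajb9 was 33.9 untreated and 288 at 4 h, and its untreated cytosol value was blank. Matrix and secreted proteins had medians below 0 in the sum at each time (-0.51, -0.50, -0.89 and -0.81), although their averaged difference was 1.03 at 0.5 h (Thbs1 2.78) and 0.43 at 1 h. Col1a1 summed to -1.44, -1.07, -1.83 and -1.12 and Fn1 to -0.67, -0.94, -1.28 and -1.01. At 4 h the averaged median was -0.44, with the chemokines Ccl7 (1.72) and Cxcl1 (1.22) higher.

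Surface proteins summed to medians of -0.23, -0.58, -0.94 and -0.64, lysosomal proteins to -0.67, -0.50, -0.68 and -0.39, and IRE1-dependent decay targets to -0.55, -0.38, -0.73 and -0.63, where Bloc1s1 averaged -1.13 at 4 h. ER entry genes summed to -0.18, -0.17, -0.21 and 0.22. Glycolytic and cytoskeletal genes had a median of -0.60 at 4 h (Actg1 -1.32, which is uncertain, and Flna -1.00), with Actb at -0.91 and Gapdh at -0.35. Cell cycle genes had a median of -0.13 at 4 h, with 3 of 26 over 2-fold lower (the cyclins Ccnd1 -1.92 and Ccne1 -1.03 and the kinase Plk1 -1.12). Ribosomal proteins lay at -0.28 at 0.5 h and -0.10 at 4 h, and translation factors at -0.06 and 0.12, with the helicase Eif4a2 at 2.07 and Pabpc1 at -1.39 at 0.5 h. At 4 h proteasome subunits stood at -0.13, oxidative phosphorylation at -0.11, heat shock at 0.01, cholesterol synthesis at 0.26 and NRF2 targets at 0.27 (the heme oxygenase Hmox1 1.12, Prdx1 -1.05). Ppp1r15b scored 8.84 in the ER untreated and 7.90 at 4 h. The 8 lowest genes at 0.5 h were Isg15 (-2.36), Ifi27l2a (-2.35), Usp18 (-2.18), Ifit1 (-2.12), Phf11d (-2.01), Rtp4 (-1.97) and Ifi44 (-1.79), most of them induced by interferon, and the RNA-binding protein Ybx3 (-1.70). Their sums of both fractions were -1.47, -1.15, -1.22, -1.25, -1.43, -1.18, -1.12 and -1.39 in that order. Over 9323 genes, 785 were over 2-fold higher and 180 lower at 0.5 h, 634 and 196 at 1 h, 582 and 109 at 2 h (437 and 173 after centring on 0.11), and 347 and 106 at 4 h (268 and 178 after centring on 0.10). These counts rest on the mean of the ER and cytosol differences, so a gene can count as higher while its sum is lower. At 0.5 h surface proteins had medians of -1.03 in the ER and 3.18 in the cytosol, but -0.23 in the sum.

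In mRNA, 4 of 8 ER chaperones and 5 of 17 aminoacyl-tRNA synthetases were over 2-fold higher at 4 h of Tg, the time with the most genes over 2-fold. The 8 highest genes were Hfm1 (2.89), Ddit3 (2.48), C230072F16Rik (2.45), Hspa5 (2.24), Atf4 (1.71), Hsp90b1 (1.66), Mlf1ip (1.66) and the folate enzyme Mthfd2 (1.58). ER chaperones had a median of 1.06 (Calr 1.24, Pdia3 1.19) and synthetases of 0.81 (Tars 1.24, Eprs 1.13, Cars 1.08, Aars 1.06). ER entry genes had a median of 0.64 with 0 of 14 over 2-fold (Tmed2 0.77, Ssr3 0.74), and ATF4 and CHOP targets of 0.36. Glycolytic and cytoskeletal genes stood at -0.35 (Myl6 -1.00), and Actb at -0.90. The 8 lowest were Gm5396 (-1.46), the splicing protein Snrpd1 (-1.24), Pax8 (-1.23), Rpl41 (-1.20), the calcium-binding S100a6 (-1.17), Ndufb10 (-1.17), the clock repressor Nr1d1 (-1.14) and Gm9385 (-1.12), of which the Gm entries are uncertain. Counts over 2-fold were 31 higher and 9 lower at 0.5 h (41 and 5 centred), 15 and 19 at 1 h (36 and 6 after centring on -0.17), 36 and 15 at 2 h, and 71 and 15 at 4 h (48 and 28 after centring on 0.11). With each column centred on its median gene, 37 of 82 were higher at 4 h. At 0.5 h the sum of both fractions left 16 genes over 2-fold in place of 40.

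Among the 8 highest genes in translational efficiency at 1 h of Tg, above the median level, were Ddit3 (3.82) and Atf4 (1.95). Ddit3 stood at 3.18, 3.82, 2.62 and 1.99 and Atf4 at 2.58, 1.95, 2.03 and 1.71 at the 4 times. The other 6 of the 8 highest at 1 h were Hist1h2bh (2.77), LOC101056094 (2.26), the histone chaperone Anp32e (1.98), Cd44 (1.97), Pigf (1.97) and Hist1h1b (1.96), of which the histones and the LOC entry are uncertain. Among the lowest were Pabpc1 (-1.85), the RNA-binding protein Ybx3 (-1.71), LOC636901 (-1.68, uncertain), Bud31 (-1.59), Ap3s1 (-1.53), Gm12693 (-1.44, uncertain) and Wdr61 (-1.43). Surface proteins had a median of 0.73 (1 of 5 over 2-fold), ER chaperones of 0.14 (0 of 8) and ribosomal proteins of -0.12 (4 of 68 higher, 2 lower; Rpl41 1.93, Rps28 1.503, Rpl17 -1.10). That last value was lower than in nearly all matched random lists (percentile 0.01). Over 2245 genes, 125 were over 2-fold higher and 84 lower at 0.5 h, 155 and 64 at 1 h (111 and 85 after centring), 105 and 40 at 2 h (70 and 71 after centring on 0.14), and 37 and 51 at 4 h. Under the strict filter 26 of 36 were higher at 4 h.

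After 30 min of DTT, footprints of secretory pathway genes had cytosol scores of the same order as their ER scores. ER chaperones had a median ER minus cytosol difference of -0.47 (1 of 19 higher, 3 lower; Dnajb11 -1.52, Hyou1 1.08), where all genes had -1.17. Surface proteins stood at -0.21 (the endocytic receptor Lrp1 1.69, Bmpr1a -1.85), lysosomal proteins at -0.14 (Npc2 -1.48, Lamp2 -1.40), ER entry genes at -1.00 (Srp54b -2.76) and ribosomal proteins at -1.87 (79 of 80 lower; Rps20 -3.25). Matrix and secreted proteins stood at 0.36 (15 of 49 higher; Col1a1 2.61, the proteoglycan Hspg2 2.41, Col5a1 2.26, Col4a2 2.06), and the median of that list was -0.13 under the strict filter. Marked minus unmarked genes came to 0.48 (0.41 to 0.55), against 3.56 in the untreated cells of the same table. Of 8315 genes, 73 were over 2-fold higher in the ER and 4879 lower (863 and 658 after centring). In mRNA the difference was 0.31 (0.20 to 0.44), with 18 genes higher and 885 lower (220 and 131 after centring on -0.86), ER chaperones at -0.71 and matrix and secreted proteins at 1.23 (Col5a2 2.92, Fn1 2.54).

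Against untreated cells, the marked genes had an ER shift of -3.36 in footprints after 30 min of DTT, -1.84 after 10 min of recovery and -0.97 after 20 min. The parts at 30 min of DTT were -0.73 in the ER and 2.66 in the cytosol, and the sum stood at 0.31. The median ER share of ER chaperone footprints was 98.3% untreated, 42.0% after DTT and 82.2% and 89.4% after 10 and 20 min of recovery. Hspa5 had a cytosol score of 8.15 untreated, 421 after DTT and then 133 and 85.2. The cytosol columns of DTT carry the limit named for Tg, with departing densities in 10.5%, 7.25% and 13.6% of marked genes found mainly in the ER against 5.53%, 1.70% and 1.53% of matched genes. The summed footprints of mRNAs with upstream reading frames had medians of 3.50, 2.23 and 1.56 against untreated cells, with Atf4 in the cytosol at 92.0 untreated, 1039.6 after DTT and then 511 and 338.

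During recovery, secretory pathway footprints were higher in the ER and lower in the cytosol than right after DTT. At 20 min the highest ER shifts were those of the multispanning Tm9sf3 (5.25), Itgb1 (5.08), Sec61a1 (4.93), Pdia3 (4.87), Tmem123 (4.81), Tfrc (4.78), Lamp2 (4.67) and Ctsb (4.64). All 22 lysosomal proteins (median 3.62; Lamp1 4.42), 19 of 19 ER chaperones (3.40; Canx 4.61, P4hb 4.34, Hsp90b1 4.15), 30 of 30 surface proteins (2.98), 47 of 49 matrix and secreted proteins (2.85; Bgn 4.30) and 28 of 36 ER entry genes (2.82; Rpn2 4.55) were over 2-fold higher. At 10 min the medians were 2.46, 2.41, 1.86, 1.81 and 1.89 in that order. Ribosomal proteins stood at 0.86 at 20 min (25 of 80 higher), ER-associated degradation at 2.39, IRE1-dependent decay targets at 2.18, cholesterol synthesis at 0.88 and immediate early genes at 0.16. The lowest were LOC100861722 (-2.14, uncertain), 2410004B18Rik (-2.06), Lmo4 (-1.78), Rabif (-1.75), the autophagy protein Map1lc3a (-1.75), Rfk (-1.65), Commd5 (-1.59) and Gm14295 (-1.52, uncertain). Marked minus unmarked genes came to 1.35 at 10 min and 1.93 at 20 min. There were 1437 genes over 2-fold higher and 256 lower at 10 min (1109 and 510 after centring on 0.23) and 2221 and 172 at 20 min (1311 and 643 after centring on 0.49).

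In mRNA, ER chaperones were also shifted to the ER during recovery. At 20 min 8 of 8 ER chaperones were over 2-fold higher (median 1.80; Ppib, a prolyl isomerase, 3.09, Canx 2.03), as were 5 of 9 matrix and secreted proteins (1.41; Mmp3 2.17) and 4 of 7 surface proteins (1.36). The other highest genes were Hist1h2bg (2.88, uncertain), Atpif1 (2.53), the ribosome-binding Rrbp1 (2.44), Ccdc47 (2.39), P4ha1 (2.28), Txnl1 (2.21) and Ifitm3 (2.18). The 8 lowest were Mrpl51 (-1.40), Ube2d2a (-1.28), the chaperone Hsph1 (-1.23), Uba3 (-1.22), Cox7c (-1.16) and LOC100048613 (-1.16), both uncertain, 1700088E04Rik (-1.15) and Rab2a (-1.15). Marked minus unmarked genes came to 0.43 at 10 min and 0.55 at 20 min, with 227 genes higher and 55 lower (130 and 113 after centring) and then 305 and 75 (160 and 153 after centring).

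Relative to the end of DTT, footprints of Atf4 were lower during recovery and those of Fos higher. The 8 mRNAs with upstream reading frames had medians of -0.90 at 10 min and -1.15 at 20 min, with 4 over 2-fold lower (Slc35a4 -2.41, Atf5 -1.81, Ppp1r15a -1.52, Atf4 -1.40). Of 20 immediate early genes, 9 were higher and 1 lower at 20 min (median 0.49; Fos 3.44, Zfp36 2.88, Nr4a1 2.61, Egr1 2.57). Ribosomal proteins stood at 0.49 (6 of 80 higher; Rps18 1.25), higher than in 100% of matched random lists, aminoacyl-tRNA synthetases at 0.43 and heat shock at 0.44 (Hsp90ab1 1.25, Hspb1 -1.34). The other highest genes were Tmem97 (1.83), Gm12657 (1.80, uncertain), Ier2 (1.77), Gbas (1.69) and Tma7 (1.57). The other lowest were 1500012F01Rik (-2.48), Lsm7 (-1.98), Ccdc167 (-1.96), Gnptab (-1.88), Hist1h2bh (-1.78, uncertain), the polyamine enzyme Sat1 (-1.74) and Gm20594 (-1.70, uncertain). ER chaperones averaged -0.40 but summed to 0.36, matrix and secreted proteins -0.62 and 0.13, surface proteins -0.57 and 0.06, lysosomal proteins -0.56 and 0.27, and ER entry genes -0.30 and 0.14. Counts over 2-fold were 89 higher and 143 lower at 10 min and 188 and 344 at 20 min, while under the strict filter 75 of 108 and 155 of 280 were higher. In mRNA they were 33 and 1 at 10 min (4 and 3 after centring on 0.25) and 31 and 1 at 20 min (4 and 7 after centring on 0.23). The genes named for mRNA at 10 min were Nucks1 (1.15), the exon junction protein Magoh (1.11), the phosphatase methylesterase Ppme1 (1.07), the Wnt receptor Ryk (1.04), A530032D15Rik (1.01) and LOC101056094 (1.21, uncertain), and on the lower side LOC101055698 (-1.09, uncertain).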

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

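The tests of constants, exchanged libraries, differing replicates and uniform carry-over in this part were chosen only after the results were seen. What drew attention was the same in each case. The median of a gene list, or of the marked genes, lay at least 0.5 from 0 (log2) in both fractions and in opposite directions under 1 treatment. The difference was not tested, since each group has 1 value per gene. Values below are the ER median minus the cytosol median, followed by the 2 medians in that order. They are set against 0, without the median of all genes beside them. The fractions also moved as a whole, as the ER share of all mRNA scores went from 41.6% untreated to 29.3% at Tg 0.5 h. Medians near the limit of 0.5 can therefore be partly a move of all genes.

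In footprints at 0.5 h of Tg, 8 lists and the marked genes were lower in the ER and higher in the cytosol than in untreated cells. The values were -5.30 for matrix and secreted proteins (-1.48, 3.82), -4.998 for lysosomal proteins (-1.54, 3.46), -4.99 for ER chaperones (-1.15, 3.83), -4.21 for surface proteins (-1.03, 3.18) and -3.91 for ER entry genes (-1.10, 2.81). They were -3.25 for targets of IRE1-dependent decay (-1.64, 1.61), -2.82 for ER-associated degradation (-0.74, 2.08), -2.74 for marked genes (-0.84, 1.90) and -1.44 for cholesterol synthesis (-0.52, 0.92). At 1 h the lists concerned were lysosomal proteins at -2.74 (-0.75, 1.99), ER entry genes at -2.56 (-0.64, 1.92), surface proteins at -2.32 (-0.76, 1.56) and matrix and secreted proteins at -2.30 (-0.66, 1.64). At 2 h they were lysosomal proteins at -2.03 (-0.76, 1.27), surface proteins at -1.87 (-1.11, 0.76) and matrix and secreted proteins at -1.83 (-1.01, 0.82). In mRNA at 0.5 h the values were -4.56 for ER chaperones (-1.09, 3.48), -3.71 for matrix and secreted proteins (-1.04, 2.67), -3.22 for surface proteins (-1.06, 2.16), -1.93 for ER entry genes (-0.93, 1.00) and -1.54 for marked genes (-0.75, 0.79). Matrix and secreted proteins stood at -1.32 in mRNA at 1 h (-0.56, 0.76), and surface proteins at -1.11 at 2 h (-0.56, 0.55).

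During recovery from DTT the directions were the other way, higher in the ER and lower in the cytosol than at the end of DTT. In footprints at 10 min the values were 2.62 for lysosomal proteins (1.05, -1.57), 2.60 for ER chaperones (1.16, -1.44), 1.81 for ER entry genes (0.93, -0.89), 1.51 for marked genes (0.57, -0.95) and 1.29 for ER-associated degradation (0.73, -0.57). At 20 min they were 3.63 for ER chaperones (1.51, -2.12), 3.62 for lysosomal proteins (1.26, -2.36), 2.93 for surface proteins (0.87, -2.06), 2.89 for matrix and secreted proteins (0.83, -2.06) and 2.81 for ER entry genes (1.01, -1.80). Marked genes stood at 2.38 (0.72, -1.66), targets of IRE1-dependent decay at 2.10 (0.74, -1.37), ER-associated degradation at 1.92 (0.69, -1.23) and cholesterol synthesis at 1.79 (0.76, -1.03). In mRNA, surface proteins stood at 1.11 at 10 min (0.58, -0.53), and at 20 min ER chaperones at 1.80 (1.00, -0.80), matrix and secreted proteins at 1.56 (0.81, -0.76) and surface proteins at 1.40 (0.73, -0.67).

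Secretory pathway genes lower in the ER and higher in the cytosol could come from the processing or from the treatment. Constants per compartment move all genes alike, which the 1.75 of marked minus unmarked genes in the cytosol at Tg 0.5 h argues against. Exchange of an ER and a cytosol library of 1 replicate was also considered. At equal weight of the replicates it would bring marked minus unmarked genes in ER against cytosol to 0. The 1.45 at Tg 1 h argues against such an exchange at that time only. At Tg 0.5 h and the end of DTT the values were 0.69 and 0.48, nearer to 0. At Tg 0.5 h strongly ER-bound marked genes had a median log2 ratio of cytosol over ER of -0.08, against -5.40 untreated. An equal exchange would also bring such genes to 1 common ratio. An exchange at Tg 0.5 h or in DTT, and one at unequal weight at any time, stay open. A uniform carry-over of ER material would give ER-bound genes 1 common log2 ratio of cytosol over ER, and at Tg 0.5 h the quartiles of 14.3% of the lists (1 of 7, cholesterol synthesis at -0.91 with 8 genes) lay apart from those of all 569 strongly ER-bound marked genes (median -0.08), so it cannot be told apart from a uniform release. Cytosol replicates that differed manyfold at Tg 0.5 h stay open. The deposited density departed from the ratio of the scores in 34.01% of strongly ER-bound marked genes against 2.22% of matched unmarked genes. Reading this as differing replicates assumes that the density was averaged over replicates. A plain mean of 2 replicate ratios, with scores averaged alike, could give the 26.3% over 1.5 times. It could not give the 7.74% below 0.5 times, which go against a plain mean. Other columns with such a departure were the ER at Tg 1 h (9.95% against 2.88%) and the cytosol through DTT and recovery (10.5%, 7.25% and 13.6% against 5.53%, 1.70% and 1.53%). Further ones were the untreated cytosol (3.88% against 0.42%), the reference for the cytosol differences under Tg, and the cytosol at Tg 1 h (3.76% against 1.80%). Release of ER-bound mRNAs by Tg or DTT also stays open, as an untested biological explanation.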

How the results depend on the processing

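The alternatives with blanks as 0, columns centred, the sum of both fractions and the deposited density were chosen only after the results were seen, while the pseudocount of 0.1, the strict filter and the lack of a filter on blanks elsewhere were planned. Of the 7 alternatives just named, centred columns and the sum of both fractions were not run on the difference of marked minus unmarked genes. Under the others no such difference changed sign, where run on it. Over all alternatives, 92 such differences or counts of genes stayed (within their interval over genes, or within 1.5 times for counts) and 56 moved. For lists 2028 medians stayed within the SD of their matched random lists, 345 moved and 38 reversed, and for named genes 1958 values stayed within 0.25, 126 moved and 7 reversed. A change of sign counts as reversed for lists outside the middle 95% of random lists and for genes over 2-fold, and otherwise as moved or not by its size. Where 2 values are given, the first is the one reported, and unless a reason is given the cause was not tested.

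Under the strict filter 24 comparisons moved and 9 did not. Fewer genes were compared, which lowers counts by construction. Genes over 2-fold went from 965 to 606, 830 to 536, 691 to 399 and 453 to 283 in Tg footprints (0.5 to 4 h), from 34 to 22 (1 h) and 86 to 46 (4 h) in Tg mRNA, from 209 to 116, 219 to 126, 145 to 77 and 88 to 36 in translational efficiency, and during DTT recovery (10, 20 min) from 232 to 108 and 532 to 280 in footprints and 34 to 7 and 32 to 6 in mRNA. The majority turned in recovery footprints (75 and 155 higher, 89 and 188 reported), in efficiency at Tg 4 h (26 higher, 37 reported) and in Tg mRNA at 1 h (12 higher, 15 reported). Marked minus unmarked genes went from 3.37 to 4.20 for ER against cytosol footprints, 1.13 to 1.40 for mRNA and 0.48 to 0.62 for footprints at the end of DTT. The ER shift went from -2.42 to -3.06, -1.53 to -1.89, -1.29 to -1.64 and -0.64 to -0.79 in Tg footprints, from -0.85 to -1.17 (1 h) and -0.48 to -0.57 (4 h) in Tg mRNA and from 1.35 to 1.44 in footprints at 10 min of recovery. The list medians that reversed were ER against cytosol footprints of cholesterol synthesis (0.92 to -0.11), efficiency of ER entry genes (-0.03 to 0.87), footprints of matrix and secreted proteins at the end of DTT (0.36 to -0.13), footprints at Tg 2 h of matrix and secreted (-0.07 to 0.19) and surface proteins (-0.11 to 0.19) and cholesterol synthesis at 10 min of recovery (-0.17 to 0.12). Lists with fewer than 5 genes above the filter and genes below it have no value here.

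With a pseudocount of 0.1, 14 comparisons moved and 19 did not. Low scores gain weight by construction. Genes over 2-fold came to 1522, 1283, 1091 and 740 in Tg footprints and to 448 and 855 in recovery footprints. The ER shift came to -3.10, -2.02, -1.69 and -0.78 in Tg footprints and to 1.48 and 2.19 in recovery, and ER against cytosol to 4.04 in footprints and 2.33 in efficiency (1.77 reported). Reversed were footprints at Tg 2 h of matrix and secreted (0.12) and surface proteins (0.084), and oxidative phosphorylation mRNA at 20 min of recovery (-0.00064 to 0.000193).

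Without a filter on blanks elsewhere 30 comparisons did not move and 3 did, ER against cytosol footprints to 3.03 (untreated) and 0.66 (end of DTT) and the footprint ER shift at Tg 1 h to -1.43. Efficiency of ER entry genes (0.14) and, in mRNA at 20 min of recovery, matrix and secreted proteins (-0.10 to 0.059) and oxidative phosphorylation (0.0048) reversed.

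With blanks as 0, 11 comparisons moved and 5 did not, with more genes and with filled blanks by construction. Genes over 2-fold turned from mostly lower to mostly higher in untreated ER against cytosol footprints (2283 of 3640) and in the mRNA ER shift at Tg 1 h (2081 of 3488) and 2 h (1714 of 3367), and from mostly higher to mostly lower in the mRNA ER shift at 10 min of recovery (1289 of 2975 higher). ER against cytosol came to 3.32 in untreated mRNA, 2.25 in untreated footprints, 0.61 in footprints and 0.67 (from 0.31) in mRNA at the end of DTT. The ER shift came to -0.88, -0.82, -0.74 and -0.52 in Tg footprints, 1.26 and 1.53 in recovery footprints (1.93 reported at 20 min) and 0.85 (from 0.55) in mRNA at 20 min. Reversed in mRNA were the ER shift of matrix and secreted proteins at Tg 4 h (-1.11 to 0.059) and ER against cytosol of surface proteins at the end of DTT (-0.01 to 0.20).

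The sum of both fractions moved 1 comparison, Tg mRNA at 0.5 h (40 to 16 genes), and left 11. It reversed 24 list medians and 7 genes, because it weighs the larger fraction where the average weighs both alike. In Tg mRNA these were, at 0.5 h, ER chaperones (1.28 to -0.060), matrix and secreted (0.36 to -0.026) and surface proteins (0.56 to -0.11), Hsp90b1 (1.61 to -0.25) and Calr (1.14 to -0.064), at 1 h ER chaperones (0.97 to -0.061) and Hsp90b1 (1.36 to -0.11), and at 2 h ER chaperones (0.86 to -0.024) and ER entry genes (0.31 to -0.039). In Tg footprints at 0.5 h they were ER chaperones (1.32 to -0.32), ER entry (0.81 to -0.18), matrix and secreted (1.03 to -0.51), surface (1.03 to -0.23) and lysosomal proteins (1.09 to -0.67), Hsp90b1 (1.85 to -0.58), Calr (2.25 to -0.064) and Fn1 (1.18 to -0.67). At 1 h they were ER chaperones (1.04 to -0.11), ER entry (0.52 to -0.17), matrix and secreted (0.43 to -0.50), surface (0.36 to -0.58) and lysosomal proteins (0.70 to -0.50) and Hsp90b1 (1.04 to -0.51), and at 2 h ER chaperones (0.96 to -0.0090). In recovery they were matrix and secreted proteins in mRNA at 20 min (-0.10 to 0.059), lysosomal proteins in footprints at 10 min (-0.21 to 0.27), and in footprints at 20 min ER chaperones (-0.40 to 0.36), ER entry (-0.30 to 0.14), matrix and secreted (-0.62 to 0.13), surface (-0.57 to 0.064) and lysosomal proteins (-0.56 to 0.27).

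The deposited density moved 1 of 5 comparisons, ER against cytosol efficiency, to 2.15. Centred columns moved 2 of 16, the genes over 2-fold in recovery mRNA, from 34 to 6 and 32 to 11, since the shift of all genes is taken out. The majority turned in Tg mRNA at 1 h (36 of 42 higher) and 4 h (37 of 82), in efficiency at Tg 2 h (68 of 143) and in recovery mRNA at 20 min (1 of 11), and was even at 10 min (3 of 6).

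No paired analysis was possible because the columns carry 1 value per gene and group, with no replicate numbers. Not run for want of counts or replicates were other normalizations and tests of counts, filters on counts, the replicate block, leaving out each replicate, fits on fewer libraries and other list tests. An 8th alternative, untreated cells as the reference for the ER shift of recovery, was also tried, asks another question and is outside these counts. Marked minus unmarked genes then had the opposite sign in all 4 comparisons, at -1.44 and -0.79 in footprints (1.35 and 1.93 reported) and -0.52 and -0.38 in mRNA (0.43 and 0.55). The depth is unknown, so what it limits cannot be said.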

Other observations

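The tests of interferon state and of separate cultures in this part, and the list of 36 genes induced by interferon, were chosen only after the results were seen. Interferon-induced genes stood out under Tg. For the 32 with complete values, summed footprints had medians of -0.82, -0.29, 0.73 and 1.01 against untreated cells at 0.5, 1, 2 and 4 h, with 12 over 2-fold lower at 0.5 h and 16 higher at 4 h. ER medians were -2.14, -0.45, 1.07 and 1.29, and cytosol medians -0.40, -0.30, 0.53 and 0.81. Isg15, a ubiquitin-like protein, scored 234, 17.3, 239, 534 and 744 in the ER from untreated to 4 h, and 535, 260, 292, 770 and 1216 in the cytosol. Ifit1 scored 43.7, 2.89, 16.5, 133 and 110 in the ER, where its deposited density at 1 h was 0.338 beside an mRNA score of 11.01, far from the ratio of the scores. Other listed genes departed likewise in the ER at 1 h, such as Rtp4 (density 0.1215, footprints 43.8, mRNA 30.7), Bst2 (0.647, 236, 88.7) and Oas1a (0.217, 18.4, 20.8). Ifit2 (0.239, 12.4, 49.8) and Irf7 (0.557, 5.98, 10.7) did not. The ER values of this list at 1 h therefore carry the limit named above for the ER at 1 h. Cultures in another interferon state could give the low values at 0.5 h if they fed both fractions. At 0.5 h the ER difference minus the cytosol difference had a median of -1.70 over the 32 genes, some of which had prompted the list. In the 14 unmarked genes whose values had not been looked at when the list was written it was -1.07 (95% interval over genes -1.66 to -0.88), beside -0.33 for all unmarked genes. This argues against that explanation as the whole cause only if the cultures weighed alike in the ER and the cytosol values. How the replicates were weighed is unknown, so cultures of unequal weight in the 2 fractions stay open. Genes induced together are not independent, and each fraction has 1 pooled value. The interval therefore does not measure a spread between cultures or libraries. No biological explanation was tested. In the DTT table the sums for 35 of the genes had medians of 0.92, 0.93 and 1.00 against untreated cells after 0, 10 and 20 min of recovery.

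Of 8315 genes, 207 were over 4-fold higher in summed footprints at the end of DTT than in untreated cells, and 44 of them, 9 of these marked, were also over 4-fold higher at 10 and 20 min of recovery. Among the more abundant were Fos (2.93, 4.68 and 6.43 at 0, 10 and 20 min), Ddit3 (4.64, 4.08 and 3.94), the immediate early Ier2 (2.07, 2.95 and 3.91), Plac8 (3.30, 3.05 and 3.14), the cytokine Il6 (2.98, 3.16 and 3.13), Gadd45g (2.85, 3.14 and 2.99) and Ch25h, the cholesterol 25-hydroxylase (2.02, 2.68 and 2.60). Ifi27l2a (2.97, 2.56 and 2.48), which is on the list of genes induced by interferon, was also among them. The inhibitor of thioredoxin Txnip (2.13, 2.28 and 2.55), the chemokine Cxcl12 (3.33, 2.59 and 2.45) and Id3 (2.33, 2.41 and 2.44) were others, and Gm20594 and 4 histone genes are uncertain. Untreated cells from another set of cultures than the DTT cells are a candidate explanation, and the share of 21.3% that stood over 4-fold at all 3 times cannot be told apart from a lasting effect of DTT, since treatment and culture would differ together.

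The ER share of all footprint scores was 41.6% in untreated cells and 31.7%, 36.7%, 40.9% and 44.4% under Tg, and 38.1%, 26.4%, 34.4% and 38.6% from untreated cells through DTT and recovery in the DTT table. For mRNA it was 41.6%, 29.3%, 34.2%, 38.0% and 41.0%, and 38.1%, 23.8%, 30.97% and 35.6%. The entries LOC101055971, C330021F23Rik, LOC101056226, Gm5148, C230062I16Rik and LOC101055820 together took between 36.1% and 66.9% of each mRNA column and at most 0.0259% of a footprint column. The mRNA shares above include these entries, so their course need not be that of most genes. The median ER share of unmarked genes in Tg mRNA was 50.5% untreated and 40.3%, 52.2%, 51.6% and 53.7% at the successive times. That median was thus near its untreated value by 1 h. It may still depend on the 6 entries, since the scaling of the scores is not stated. They took 66.9% of the cytosol mRNA column at 1 h of Tg against 58.0% untreated. In the mRNA of the DTT table the median ER share of unmarked genes was 46.8%, 34.5%, 37.3% and 38.3%.

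Lists with fewer than 5 complete genes are given here once. None of the 6 nuclear-retained RNAs (0) is in the tables. Of 12 leukocyte markers in the tables, 2 had any footprint value, and the highest was Cd14 at 9.66. Of 10 epithelial markers 5 had one (Krt19 at most 7.44), and of 10 endothelial markers 6 (Egfl7 at most 4.98). Of 11 genes of skeletal muscle and adipocytes 2 had one, with Acta1 at 563, which is uncertain.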
